A study of Homo sapiens with 8 samples.

How the data were processed

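RNA of 4 stable SKOV3 lines was measured on 8 Agilent 60K human expression arrays, 1 array for each line under each oxygen label. Per the labels, cells grown in medium with 10% serum were starved of it and then given 10 µM LPA for 16 h in normoxia or hypoxia. The group of each array was taken from its labels. Nothing in the labels says that arrays came from separate cultures, and no condition has a second array. P-values therefore measure only how far line differences vary between the oxygen labels, which in part may be technical. Where that variation is large, a line without called genes may still differ from shControl.

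The authors deposited 1 Feature Extraction file per array (version 11.0.1.1, per the file headers), whose values are intensity on a linear scale. Per the file headers, spots were background-subtracted and corrected for spatial trend. The 4 normoxia-labelled arrays were scanned in 2 channels and extracted with a 2-colour protocol that includes linear and lowess dye normalization, so that their green processed intensity depends in part on the red channel. The 4 hypoxia-labelled arrays were scanned in 1 channel, in a separate scan, and extracted with a 1-colour protocol, per the file headers. The labels name Cy3 (green) alone, and what RNA the red channel held is not stated. In the deposited files of the 2-channel arrays, the log ratio is log10 of red over green, and the p-value beside it comes from the extraction software's error model within 1 array. Both were used only to describe the red channel. The authors' value table holds intensity as well: each value lay within 0.5% of the green processed signal of the same spot, so its scale is linear and uncentred, and it was not normalized between arrays. Its medians were 18.5 to 20.1 on the normoxia-labelled arrays and 55.5 to 60.5 on the hypoxia-labelled ones.

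Each array held 62976 spots, of which 4259 were controls and were left out before the scaling to the 75th percentile. The rest covered 50599 distinct probes. Spots marked as non-uniform or as population outliers were left out on that array, 489, 262, 240 and 280 on the normoxia-labelled arrays of shControl, shGNA12, shGNA13 and shGNAi2 and 295, 269, 237 and 222 on the hypoxia-labelled arrays. Signals were green processed signals on the log2 scale minus each array's 75th percentile, which was 334.2 to 376.4 intensity units under the normoxia label and 590.8 to 667.9 under the hypoxia label. Spots of 1 probe were averaged. Among the 902 probes printed in 10 spots, the SD between spots was taken where every spot was well above background. Its median per array was 0.0571 to 0.0802 on the log2 scale. Probes well above background on at least 2 of 8 arrays were kept. Gene names came from the RefSeq accession in the files, matched without version to a RefSeq gene table of the human assembly GRCh38.p14 that was used for names alone. Of 30878 probes with such an accession 28174 matched, and 22425 of all distinct probes were left without a symbol and took no part in counts of genes. The probe with the highest mean signal stood for its gene, which gave 17126 genes out of 20503 on the array, 13225 of them above background on all 8 arrays. After outlier marks 75 gene values were missing.

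Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in an additive model of line and oxygen label over all 8 arrays. The model leaves 3 residual degrees of freedom, to which limma's prior added 1.93, with a prior SD of 0.259. The 5 comparisons were each knockdown line with shControl, shGNA12 with the mean of shGNA13 and shGNAi2, and the hypoxia with the normoxia label, where the pairs share a line. Whether a line's difference depends on the oxygen label could not be tested per gene. Called genes had a Benjamini-Hochberg adjusted p under 0.05. The 24 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation and with fry. Between single arrays no test was made, and a list's median was placed among 10000 random lists of its size drawn from 20 bins of mean expression.

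Named genes were, per comparison, the targeted genes, the 10 per direction with the largest change among called genes that moved the same way in every pair of arrays, and up to 4 members per list. Where fewer passed, places went to genes with the smallest unadjusted p that differed by at least 1 on the log2 scale in each pair. Of the lists 23 are reported here, and of the genes chosen only part. A gene not well above background on any array of a label has only a bound there. Its fold is given as "at least N-fold": the bright label's mean against the dim label's mean of, per array, the higher of the lowest signal well above background and the gene's own. Groups, tests, lists, named genes and most alternatives were fixed before the data were examined. A rule for genes above background on all 8 arrays, another for single arrays (at least -2 on 1 of them), ERBB2 in the label check, a list of autonomic neuron markers, fits without both shGNAi2 arrays, signals before dye normalization and targeted genes within each label were added afterwards.

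The alternatives were quantile normalization, median centring, normexp background correction (offset 50), no filter, a filter on all 8 arrays, the mean of a gene's probes, the authors' value table, a trended and robust variance, no block, a fold threshold and each array or line left out. The plan named the mean spot and background signals for normexp, but the files used here held the median spot signal, which was used. All arrays came from 1 slide, and the scan follows the oxygen label exactly. Scan as a block is therefore already the oxygen term in the line comparisons, and for the oxygen label it was not run, since the scan and the label cannot be told apart.

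The fits were tested on simulated data of 17051 genes with 200 changed at the fitted spread. For shGNA12 with shControl they recovered 0%, 40.3% and 89.4% of genes changed by 1, 2 and 4 on the log2 scale, with 5 false calls of 91. For the oxygen label they recovered 13.4%, 85.1% and 92.4%, with 15 false calls of 142, which is above the nominal rate. In the data 65.4% of genes were called between the oxygen labels, a far larger share than was changed here. These rates therefore do not carry over to that comparison. Of 24 simulated lists, the 1 that was shifted was called and 0 of the others. The simulated noise was independent between genes, whereas estimated correlations within lists of the data reached 0.395 (cholesterol synthesis). The simulation therefore does not show how often camera calls unshifted lists whose members are correlated.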

Results

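Gene expression was measured on 8 Agilent 60K human arrays, 1 for each of 4 stable lines under each of 2 oxygen labels. The lines derive from SKOV3, an established ovarian carcinoma line, and are labelled as carrying a control hairpin (shControl) or a hairpin against GNA12, GNA13 or GNAI2 (shGNA12, shGNA13, shGNAi2). GNA12 and GNA13 encode alpha subunits of heterotrimeric G proteins that couple receptors to the actin cytoskeleton, and GNAI2 encodes an alpha subunit that inhibits adenylyl cyclase. Per the labels, all cells were starved of serum and given 10 µM lysophosphatidic acid (LPA), a lipid that acts through such receptors, for 16 h in normoxia or hypoxia. The series is described as a search for genes and pathways that LPA drives through GNA12 in ovarian cancer. Between 54.97% and 56.45% of spots lay well above background on the 4 normoxia-labelled arrays and between 64.5% and 70.05% on the 4 hypoxia-labelled arrays, and 0 spots were saturated. No condition had a second array, so the number of arrays limits the precision.

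By the probe used for each gene, GNA12, GNA13 and GNAI2 were below shControl in the line that targets them on the normoxia-labelled arrays. On the hypoxia-labelled arrays they were above shControl in that line. GNA12 differed by -0.56 on the log2 scale (0.677-fold) on the normoxia-labelled shGNA12 array and by 0.34 (1.26-fold) on the hypoxia-labelled one. GNA13 differed by -1.38 (0.385-fold) in the shGNA13 line under the normoxia label and by 0.18 (1.14-fold) under the hypoxia label. GNAI2 differed by -0.39 (0.761-fold) in the shGNAi2 line under the normoxia label and by 1.48 (2.78-fold) under the hypoxia label. A second probe of GNA12 gave -0.87 and -0.17, and a second probe of GNA13 gave -0.80 and 0.24, in the same order of labels. Over both labels, limma gave a log2 difference of -0.11 (SE 0.32, adjusted p = 0.997) for GNA12, -0.60 (SE 0.47, adjusted p = 1) for GNA13 and 0.54 (SE 0.51, adjusted p = 0.775) for GNAI2, with 2 arrays against 2. The sign turned for GNA12 without the normoxia-labelled shControl array (0.01) or the normoxia-labelled shGNA12 array (0.36), for GNA13 without the normoxia-labelled shGNA13 array (0.12) and for GNAI2 without the hypoxia-labelled shGNAi2 array (-0.33). By the probes used, the targeted genes went against the line labels on the hypoxia-labelled arrays. Arrays are therefore named here by their labels only, and each direction below is a direction between labels.

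**Figure D1:**
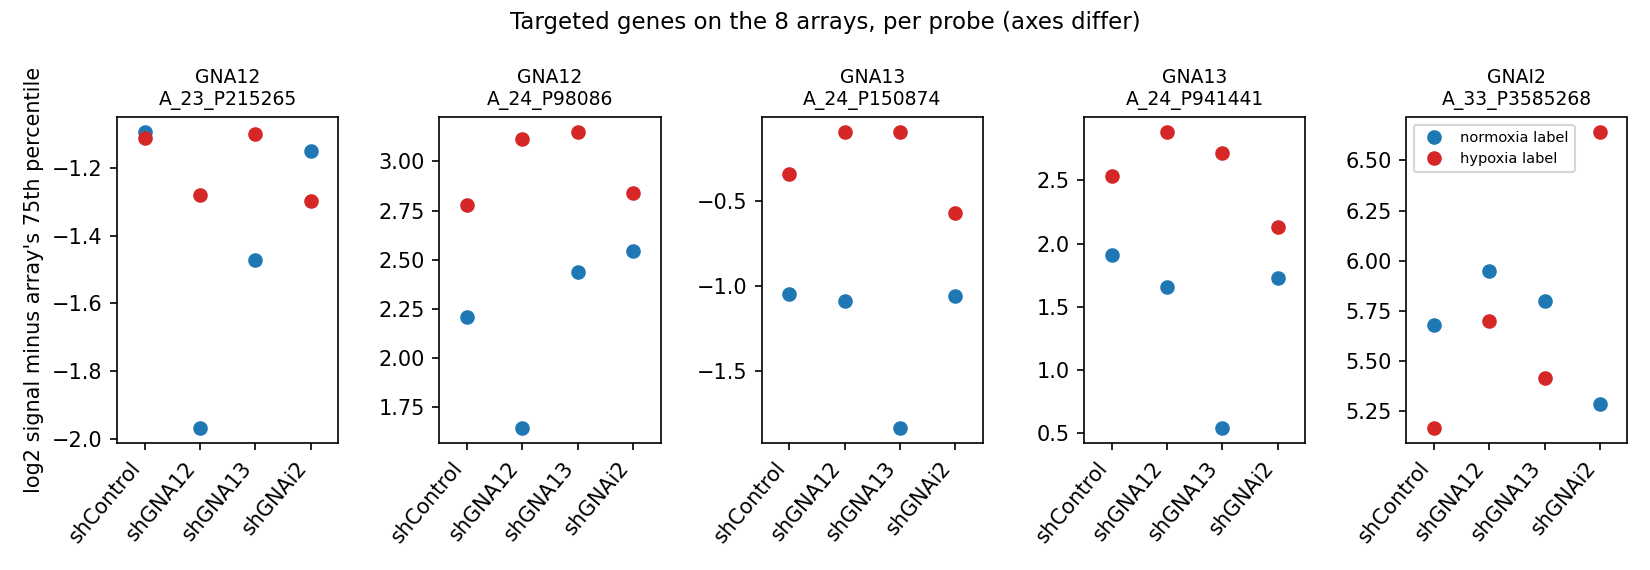
Level of each targeted gene in the 4 lines, 1 panel per probe, as log2 signal minus the array's 75th percentile, with normoxia-labelled arrays in blue and hypoxia-labelled arrays in red (1 point per array, and vertical axes differ between panels). On the normoxia-labelled arrays the main GNA13 probe, A_24_P941441, lay 1.38 lower in shGNA13 than in shControl, whereas on the hypoxia-labelled arrays it lay 0.18 higher.

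The arrays labelled hypoxia carried high signals of genes of neurons and neuroendocrine cells that the arrays labelled normoxia did not measure. STMN2, a microtubule regulator of neurons, was at least 5860-fold higher (n = 4 arrays per label), and UCHL1, a neuronal deubiquitinase, at least 5110-fold higher. CHGA, a protein of neuroendocrine secretory granules, was at least 1710-fold higher and SOX11 at least 1140-fold higher. STRA6, BEX1, KIF1A, PXDN and TMEM229A were at least 1350-fold, 888-fold, 724-fold, 717-fold and 666-fold higher. In the other direction, COX7B2 was at least 1870-fold, HOXB2 at least 1380-fold and AMIGO2 at least 751-fold lower. CFAP251 was at least 702-fold lower, PLOD2, a collagen lysyl hydroxylase, at least 620-fold and APCDD1L at least 560-fold. ANXA1 fell by 12.29 on the log2 scale (SE 1.16), with 1 of the 4 hypoxia-labelled arrays measuring it. MSN fell by 10.76 (SE 0.75, 1 of 4), P3H2 fell by 10.96 (SE 0.47, 2 of 4) and NNMT fell by 10.77 (SE 0.88, 2 of 4). Adjusted p-values from limma of the 20 genes that the naming rule chose, 19 of them given here, lay between 3.11e-05 and 0.000883. The rule admitted only called genes that moved the same way in all 4 lines.

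Among genes measured on all 8 arrays, chosen by a rule added after the values were seen, RGS5 rose by 10.15 on the log2 scale (SE 0.41), the neuropeptide gene NPY by 9.75 (SE 0.31), DPYSL3 by 9.42 (SE 0.27) and VGF by 9.03 (SE 0.35). RAMP1, MDK, TLX2, SLIT3, LAMP5 and BEX2 rose by 8.80, 8.21, 8.12, 8.02, 7.42 and 7.25. CD70 differed by -9.92 (SE 0.15), SFN by -9.50 (SE 0.23), IER3 by -8.45 (SE 0.28) and CDA by -8.38 (SE 0.17). WFDC21P, MEIOB, GADD45B, S100A2, UCA1 and HMOX1, which encodes a heme oxygenase, differed by -9.09, -8.01, -7.85, -7.84, -7.81 and -7.72. ERBB2, a receptor tyrosine kinase known for high expression in SKOV3, stood at 3.55 ± 0.33 (log2 signal minus the 75th percentile, SD, n = 4) under the normoxia label and -1.16 ± 0.48 under the hypoxia label, a fall of 4.71 (SE 0.32, limma adjusted p = 0.000376). That gene was added to the label check after other values were seen.

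**Figure D2:**
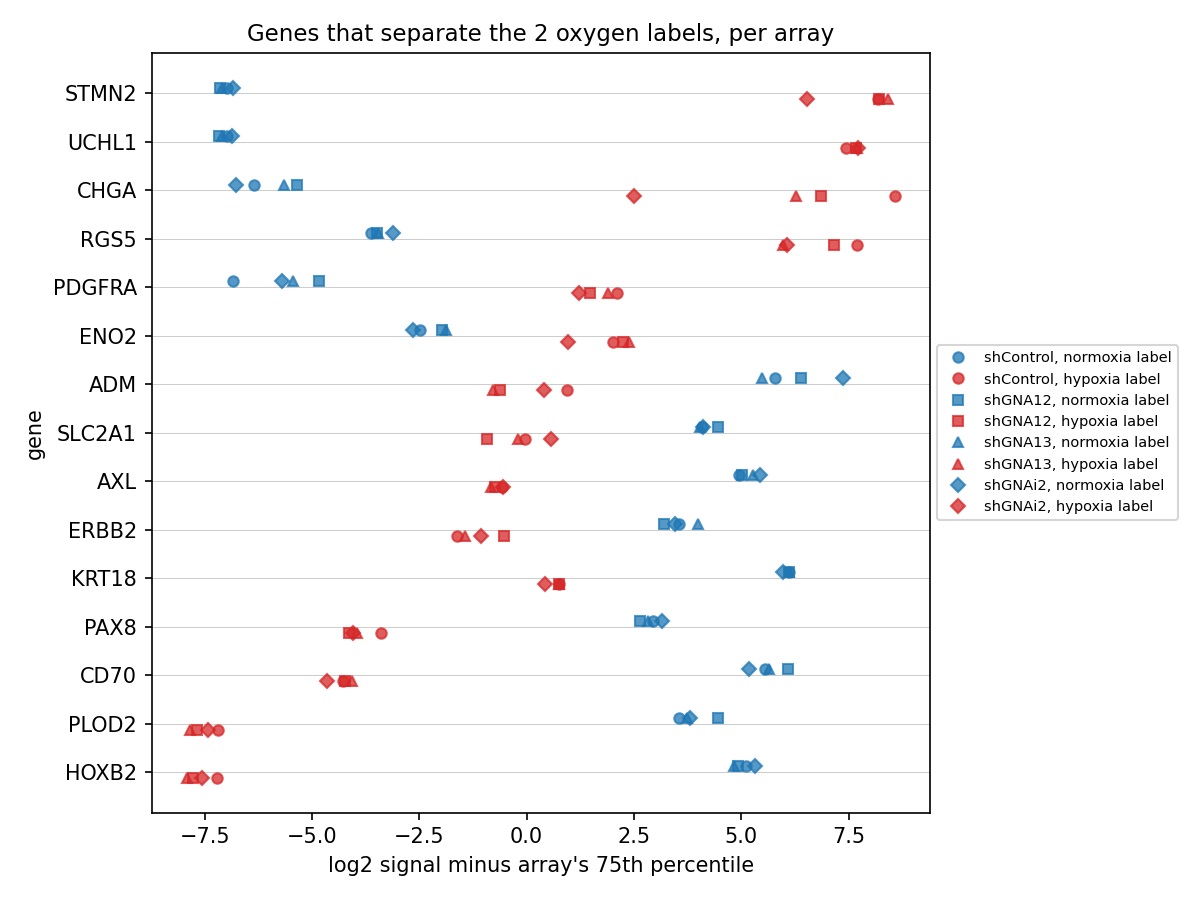
Level of 15 genes on each of the 8 arrays, on the horizontal axis as log2 signal minus the array's 75th percentile, with normoxia-labelled arrays in blue, hypoxia-labelled arrays in red and a marker shape per line; signals not well above background are drawn as measured. For each gene the 4 arrays of one label lie apart from the 4 of the other: ERBB2 averages 3.55 under the normoxia label and -1.16 under the hypoxia label.

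In all, 11208 of 17126 genes differed between the labels (limma, Benjamini-Hochberg adjusted p under 0.05), 65.4% of those tested. Of these, 5305 were higher and 5903 lower under the hypoxia label, and 7942 differed by at least 1 and 902 by at least 5 on the log2 scale. The median difference of all genes was -0.03, and it moved to -0.75 with median centring, -0.32 with normexp background and -0.11 with quantile normalization, so directions are relative to the scaling. Of 157 listed or named genes with more than 1 kept probe, 27 had a probe of the other sign between the labels. For shGNA12, shGNA13 and shGNAi2 with shControl the count was 42, 47 and 44, and for shGNA12 with the other knockdown lines 28. Of genes called between the labels, the share that were higher was 47.3%. It was 25.2% with median centring, 32.7% with normexp background and 37.5% with genes measured on all 8 arrays. Log2 signals correlated across kept genes with r between 0.983 and 0.986 within the normoxia label and between 0.918 and 0.985 within the hypoxia label. Across labels r was between 0.734 and 0.772, and genes are not independent replicates. The 4 hypoxia-labelled arrays were scanned and extracted apart from the others, so the oxygen label and the scan cannot be told apart.

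HIF target genes, which low oxygen switches on through the HIF transcription factors, were mostly lower under the hypoxia label. Of 27 measured, 3 rose, 15 fell and 9 did not pass, the same counts as when adjusted over the list alone. PLOD2 was at least 620-fold lower, ADM, the adrenomedullin gene, fell by 6.27 (SE 0.41), BHLHE40 fell by 4.56 (SE 0.65) and STC2 was at least 9.60-fold higher. The list median was -0.99, or -0.65 with quantile normalization and -1.72 with median centring, and by line it was -0.73 in shControl, -1.40 in shGNA12, -0.78 in shGNA13 and -0.63 in shGNAi2 (1 array against 1 each). These medians lay at percentiles 7.18, 0.02, 4.66 and 8.03 among 10000 random lists matched on mean expression. The list did not pass camera (adjusted p = 0.0593, or 0.868 with an estimated correlation), whereas fry, which tests whether members move one way on balance, gave an adjusted p of 0.0196. Of 22 glycolysis genes, 3 rose, 17 fell and 2 did not pass, also when adjusted over the list alone (median -1.75, camera adjusted p = 0.014, adjusted p = 0.809 with an estimated correlation). The lactate exporter gene SLC16A3 fell by 4.96 (SE 0.32) and the glucose transporter gene SLC2A1 fell by 4.31 (SE 0.32), while ENO2, an enolase of neurons, rose by 4.14 (SE 0.19) and PFKM rose by 4.07 (SE 0.22). Genes of neurons moved with these groups: STMN2 was at least 5860-fold higher on the same arrays.

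Of 32 cell cycle genes measured, 29 fell, 30 when adjusted over the list alone, and 0 rose. Their median was -1.37 (camera adjusted p = 1.8e-07, adjusted p = 0.732 with an estimated correlation). CDC20, PLK1, CCNB1 and AURKB, all of which act in mitosis, differed by -3.10 (SE 0.15), -3.02 (SE 0.16), -2.68 (SE 0.16) and -2.63 (SE 0.17). Of 26 oxidative phosphorylation genes, 22 fell and 0 rose (median -1, camera adjusted p = 5.66e-05, adjusted p = 0.732 with an estimated correlation). CYC1 stood at -2.76 (SE 0.18) and SDHB at -2.36 (SE 0.18). Of 13 heat shock genes, 10 fell and 1 rose (median -1.56, camera adjusted p = 0.0145, adjusted p = 0.732 with an estimated correlation), BAG3 at -3.70 (SE 0.54) and HSPA1A at -2.49 (SE 0.26). For each of the last pair of lists, counts adjusted over the list alone were the same. On the same arrays genes of neurons were higher, STMN2 by at least 5860-fold. With quantile normalization the medians of oxidative phosphorylation and heat shock genes were -0.45 and -0.92, and with median centring those of oxidative phosphorylation and cell cycle genes were -1.72 and -2.09.

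Of 22 YAP-TAZ target genes, 16 fell and 3 rose, also when adjusted over the list alone (median -3.16, or -3.05 with unmeasured members at their bound, camera adjusted p = 0.0111, adjusted p = 0.732 with an estimated correlation). The receptor tyrosine kinase gene AXL fell by 5.85 (SE 0.15), FOXF2 was at least 49.5-fold and ANKRD1 at least 29.5-fold lower, and FJX1 at least 44.3-fold higher. Of 25 SRF-MRTF targets, many of them genes of the actin cytoskeleton, 15 fell and 4 rose, with FHL2 at -5.78 (SE 0.34), TPM2 at -3.70 (SE 0.48) and ACTA2 at least 21.9-fold higher. The list passed camera (median -1.16, or -0.63 with quantile normalization and -1.88 with median centring, camera adjusted p = 0.0483, adjusted p = 0.868 with an estimated correlation). Of 19 NF-kB and inflammatory cytokine genes, 12 fell and 3 rose (median -2.16, camera adjusted p = 0.031, adjusted p = 0.732 with an estimated correlation). The chemokine genes CXCL2 and CXCL1 differed by -6.18 (SE 0.28) and -5.81 (SE 0.33). CXCL3 was at least 23.4-fold lower and CCL2 at least 16-fold higher. In these lists too, the counts were unchanged when adjusted over the list alone. The same arrays carried the high signals of neuronal genes, with UCHL1 at least 5110-fold higher.

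Of 14 fibroblast markers, 8 rose, 1 fell and 5 did not pass (median 4.82, or 3.70 with unmeasured members at their bound and 1.99 with normexp background, camera adjusted p = 0.0111, adjusted p = 0.732 with an estimated correlation). THY1 rose by 8.96 (SE 0.23, measured on 1 of 4 normoxia-labelled arrays), PDGFRA was at least 82.1-fold higher, and the collagen gene COL1A2 fell by 7.24 (SE 1.49, measured on 2 of 4 hypoxia-labelled arrays). THY1 is also expressed by neurons. Of 20 p53 targets, 10 rose, 2 fell and 8 did not pass (median 0.74, or 0.02 with median centring, camera adjusted p = 0.0387, adjusted p = 0.809 with an estimated correlation). TP53INP1 stood at 4.54 (SE 0.21), GDF15 at 3.95 (SE 0.33) and CDKN1A, a cell cycle inhibitor gene, at least 6.85-fold higher. In both lists counts adjusted over the list alone were the same, and the high signals of neuronal genes such as STMN2, at least 5860-fold higher, lay on the same arrays.

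The other 15 lists did not pass camera between the oxygen labels, the HIF targets among them. Of 17 MAPK output genes, 11 rose and 4 fell (median 1.60, or 0.88 with median centring, camera adjusted p = 0.119), with DUSP6 at 6.88 (SE 0.64) and IL1RAP at least 45.1-fold lower. Of 22 AP-1 and immediate early genes, 5 rose and 10 fell (median -0.78, or -1.50 with median centring, adjusted p = 0.249), with FOSL1 at -5.62 (SE 0.14) and IER3 at -8.45 (SE 0.28). Of 11 G protein alpha subunits, 7 rose and 2 fell (median 0.76, or 0.04 with median centring and 1.25 with quantile normalization, adjusted p = 0.357), with GNAI1 at 1.99 (SE 0.23). GNAI3 stood at -2.58 (SE 0.13) by the probe used, but a second probe, measured on all 8 arrays, went the other way at 0.96. Of 25 genes of the unfolded protein and integrated stress response, 4 rose and 13 fell (median -0.85, adjusted p = 0.0799), with the serine synthesis gene PHGDH at least 256-fold higher and ATF5 at -3.99 (SE 0.29). Of 21 cholesterol synthesis genes, 6 fell, or 3 when adjusted over the list alone, with NSDHL at -1.65 (SE 0.25) and MVK at -1.29 (SE 0.20, list median -0.45, adjusted p = 0.137). The medians of the last pair of lists, the stress response and cholesterol synthesis, were -0.51 and -0.27 with quantile normalization and -1.57 and -1.17 with median centring.

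Of 22 mesenchymal genes, 8 rose and 11 fell, 12 when adjusted over the list alone (median -1.01, or -1.73 with median centring, camera adjusted p = 0.717), with SPARC at 7.07 (SE 0.58) and CD44 at -5.62 (SE 0.61), or 0.08 by a second, dimmer probe. Of 20 epithelial genes, 10 rose and 7 fell, 8 when adjusted over the list alone, with a median of 0.47 that turns with the scaling and a mean of -0.22 (adjusted p = 0.686). The keratin gene KRT18 fell by 5.40 (SE 0.12) and DSP, a desmosome gene, was at least 430-fold lower. Of 16 ovarian carcinoma markers, 4 rose and 5 fell, with a median of 0.07 that turns with the scaling (adjusted p = 0.864), PAX8 at -6.78 (SE 0.18) and EPCAM at 4.44 (SE 0.61, measured on 1 of 4 normoxia-labelled arrays). Of 19 extracellular matrix proteolysis genes, 6 rose and 6 fell (median -0.10, mean 0.53, adjusted p = 0.929), with TIMP3 at least 170-fold higher and PLAU at -5.33 (SE 0.61). Of 28 interferon response genes, 8 rose and 6 fell, 5 when adjusted over the list alone (median -0.26, mean 0.18, adjusted p = 0.815), with IRF7 at least 95.2-fold higher. Of 14 genes of LPA receptors and metabolism, 3 rose and 5 fell, with LPAR1 at 2.71 (SE 0.43, measured on 3 of 4 normoxia-labelled arrays) and a median of 0.37 that turns with the scaling (adjusted p = 0.929). Of 15 leukocyte markers, 5 rose, or 4 adjusted over the list alone, and 1 fell, with a median of 0.21 that turns with the scaling and a mean of -0.25 (adjusted p = 0.795). Of 7 endothelial markers, 1 rose and 1 fell (median -0.04, mean 0.14, adjusted p = 0.897). With quantile normalization, median centring and normexp background the median was -0.41, -0.82 and -0.55 for extracellular matrix proteolysis, -0.76, -0.98 and -0.50 for interferon response and -0.58, -0.76 and -0.45 for endothelial markers. Camera passed 9 of the 24 lists, 5 with quantile normalization and 4 with median centring, and 0 with an estimated correlation, while fry passed 14, and its mixed test, which asks for change in either direction, passed 24.

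**Figure D3:**
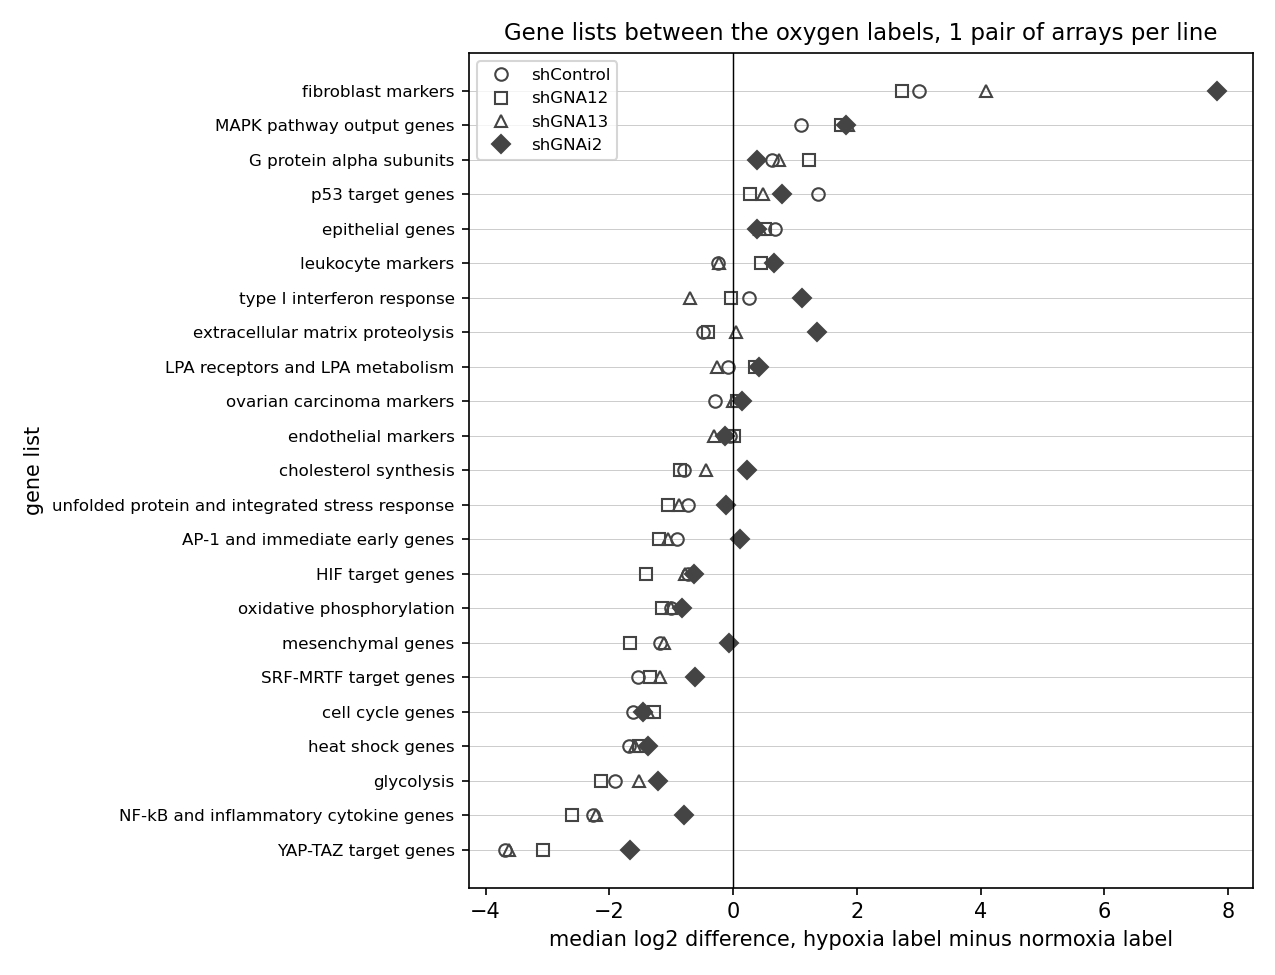
Median log2 difference of each of 23 gene lists, the hypoxia-labelled minus the normoxia-labelled array of the same line, with a marker shape per line (1 array against 1, gene lists on the vertical axis). Medians of HIF target genes lie between -1.40 and -0.63, to the left of 0 in all 4 lines.

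For the shGNA12 line, no gene passed against shControl (limma, 0 of 17126, smallest adjusted p = 0.997). At an unadjusted p under 0.05 there were 493 genes, and each other setting that kept all 8 arrays also gave 0. Without the hypoxia-labelled shControl array limma called 1 gene in each knockdown line, PSMC1, which is named here after its values were seen and whose second probe gave 0.08, -0.13 and 0.08 in shGNA12, shGNA13 and shGNAi2 over all arrays. Of the genes named by their unadjusted p and a difference of at least 1 under both labels, 3 were measured on all 4 arrays: ALCAM at 1.29 (SE 0.17) and INHBA, an activin subunit gene, at 1.11 (SE 0.21) above shControl, and ICAM5 at -1.12 (SE 0.23). NRP2, a co-receptor for semaphorins and VEGF, stood at 2.13 (SE 0.24, measured on 2 shGNA12 and 1 shControl array, and 0.33 and 1.01 by its other probes) and SALL4 at -2.31 (SE 0.40, measured on 1 array of each line). Genes of the unfolded protein and integrated stress response lay above shControl, with a median of 0.64 over 25 members. Of these 0 passed, also when adjusted over the list alone, with SLC7A11, a cystine transporter gene, at 3.33 (SE 1.12), DDIT3 at 1.95 (SE 0.57), CHAC1 at 1.83 (SE 0.57) and HERPUD1 at 1.26 (SE 0.39). Cholesterol synthesis genes lay below shControl, with a median of -0.40, CYP51A1 at -2.04 (SE 0.88) and LSS at -0.80 (SE 0.23). CYP51A1 stood at -3.81 under the normoxia label and at -0.26 under the hypoxia label. Camera passed both lists (adjusted p = 3.41e-09 and 0.00114), and with an estimated correlation neither (adjusted p = 0.825 for both).

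Of the 24 lists camera passed 6 for shGNA12, and the other 4 were cell cycle genes (median 0.20, adjusted p = 0.000719), interferon response genes (median 0.30, adjusted p = 0.0194), oxidative phosphorylation genes (median -0.15, adjusted p = 0.0194) and leukocyte markers (median -0.38, adjusted p = 0.013). With an estimated correlation the adjusted p of each was 0.825, and fry passed 0 lists. On the hypoxia-labelled shGNA12 array the medians of cell cycle and oxidative phosphorylation genes were 0.34 and -0.32 (percentiles 100 and 0). Under the normoxia label they were 0.06 and -0.02 (percentiles 90.09 and 57.65). On that hypoxia-labelled array GNA12 stood at 0.34 from shControl by the probe used and at -0.17 by a second probe. With normexp background the medians of interferon response genes and leukocyte markers were 0.10 and -0.25. With either of the shGNAi2 arrays left out camera passed 10 lists. In oxidative phosphorylation, NDUFB8 stood at -0.49 (SE 0.26), in the cell cycle list E2F1 at 0.45 (SE 0.42), and among leukocyte markers NKG7 at -1.25 (SE 0.60), none passing. HIF target genes had a median of 0.21 (adjusted p = 0.089), SRF-MRTF targets -0.01 and YAP-TAZ targets 0.21, and none of these 3 lists passed. The YAP-TAZ median was 0.05 with normexp background. It was -0.04 on the normoxia-labelled shGNA12 array alone and 0.74 on the hypoxia-labelled one. The median of fibroblast markers, 0.47, fell below 0 under normexp background, at -0.29.

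For the shGNA13 line, again no gene passed (limma, 0 of 17126, with 403 at an unadjusted p under 0.05 and smallest adjusted p = 1). Each other setting that kept all 8 arrays also gave 0. LPAR1, a receptor for LPA, stood at 3.22 above shControl (SE 0.60, measured on both shGNA13 arrays and 1 shControl array), and it was the single gene that passed when adjusted over the list of LPA receptors and metabolism alone. PTPRJ at 1.11 (SE 0.19), DUSP10 at 1.18 (SE 0.20) and ALCAM at 1.13 (SE 0.17) were measured on all 4 arrays, and HIC1, a transcriptional repressor gene, stood at -1.49 (SE 0.23, measured on 1 shGNA13 and 2 shControl arrays). Camera passed 3 lists, each with an adjusted p of 0.87 with an estimated correlation, and in each 0 members passed. Cell cycle genes had a median of 0.22 (adjusted p = 7.37e-07, or 0.87 with an estimated correlation), with KIF11 at 0.48 (SE 0.25). The unfolded protein and integrated stress response had a median of 0.20 (adjusted p = 0.0188), with SLC7A11 at 1.83 (SE 1.12), and oxidative phosphorylation genes had a median of -0.19, or -0.12 with quantile normalization (adjusted p = 0.0085), with ATP5F1B at -0.50 (SE 0.33). Fry passed 0 lists. Camera passed 7 lists without the normoxia-labelled shControl array, 5 with either of the shGNA12 arrays left out, 6 with either of the shGNAi2 arrays left out and 1 without the normoxia-labelled shGNA13 array.

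For the shGNAi2 line, no gene passed (limma, 0 of 17126, with 844 at an unadjusted p under 0.05 and smallest adjusted p = 0.73). Each other setting that kept all 8 arrays also gave 0. LMO1 stood at -2.84 (SE 0.36) and AUTS2 at -1.23 (SE 0.18, or -0.35 and -0.19 by its other probes), both measured on all 4 arrays, and DUSP10 at 1.25 (SE 0.20) and TRIB2 at 2.73 (SE 0.43, measured on 2 shGNAi2 and 1 shControl array). MAPK output genes had a median of 0.86, with SPRY1, an inhibitor of receptor tyrosine kinase signalling, at 3.04 (SE 1.31) and PHLDA1 at 2.06 (SE 0.41). Interferon response genes had a median of 0.77, with IFITM1 at 3.70 (SE 1.58), and mesenchymal genes 0.85, with the fibronectin gene FN1 at 3.18 (SE 1.70). Fibroblast markers had a median of 1.11 and did not pass (camera adjusted p = 0.084, or 0.585 with an estimated correlation). Camera passed 11 lists, 10 of them above shControl, each with an adjusted p of 0.585 with an estimated correlation, and gave MAPK output, interferon response and mesenchymal genes an adjusted p of 0.00205, 0.00122 and 0.00205. Extracellular matrix proteolysis genes had a median of 0.64 and SRF-MRTF targets of 0.50 (adjusted p = 0.00205 for each). Heat shock genes had a median of 0.36 (adjusted p = 0.00768) and cholesterol synthesis genes of 0.60 (adjusted p = 0.00878). Medians were 0.39 for YAP-TAZ targets (adjusted p = 0.0122), 0.53 for AP-1 genes (adjusted p = 0.0288) and 0.29 for the unfolded protein and integrated stress response (adjusted p = 0.0397). The YAP-TAZ median was 1.17 on the hypoxia-labelled shGNAi2 array alone and 0.06 on the normoxia-labelled one. The p53 targets lay below (median -0.28, adjusted p = 0.0377). With normexp background the medians were 0.36 for interferon response genes and 0.30 for extracellular matrix proteolysis. In each list 0 members passed, also when adjusted over the list alone, and fry passed heat shock genes (adjusted p = 0.0187). On the hypoxia-labelled shGNAi2 array alone, where the neuroendocrine gene CHGA stood at -6.08 from shControl, and on the normoxia-labelled one alone, the medians were 2.04 and 0.21 for fibroblast markers, 0.90 and -0.11 for extracellular matrix proteolysis, 0.85 and 0.05 for SRF-MRTF targets, 1.83 and 0.03 for MAPK output genes, 1.44 and 0.12 for mesenchymal genes and 1.15 and -0.01 for cholesterol synthesis. Without the hypoxia-labelled shGNAi2 array, camera passed 2 lists, and without the normoxia-labelled one limma called 373 genes.

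Set against the mean of the other knockdown lines, a contrast without the shControl levels in a fit that still holds those arrays, no gene differed in shGNA12 (limma, 0 of 17126, with 405 at an unadjusted p under 0.05 and 0 by each of 19 other settings). Cholesterol synthesis genes lay lower, with a median of -0.78, CYP51A1 at -2.37 (SE 0.76) and HMGCS1 at -1.37 (SE 0.48). Genes of the unfolded protein and integrated stress response lay higher, with a median of 0.50, or 0.30 with normexp background, DDIT3 at 1.61 (SE 0.49) and TRIB3, a target of the stress factor ATF4, at 1.20 (SE 0.23). AUTS2 stood at 1.22 (SE 0.16, or 0.13 and 0.48 by its other probes), NRP2 at 1.83 (SE 0.20, or 0.49 and 0.05, measured on 2 shGNA12 arrays and 3 of the other 4) and ICAM5 at -1.26 (SE 0.20). Camera passed cholesterol synthesis (adjusted p = 1.28e-09) and the stress response (adjusted p = 3.17e-05), each with an adjusted p of 0.729 with an estimated correlation. It also passed heat shock genes (median -0.25, adjusted p = 6.54e-05, adjusted p = 0.432 with an estimated correlation) and extracellular matrix proteolysis (median -0.17, adjusted p = 0.0156, adjusted p = 0.983 with an estimated correlation). Fry passed heat shock genes (adjusted p = 0.0084). In each of these lists 0 members passed, also when adjusted over the list alone. Camera passed 12 lists without the normoxia-labelled shGNA12 array, 7 without the hypoxia-labelled one and 11 without the normoxia-labelled shGNAi2 array. Differences between the lines under the normoxia and under the hypoxia label correlated across 13152 genes with r between 0.004 and 0.071 for the same line, against 0.025 to 0.1 for different lines.

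Within the normoxia label, where each targeted gene was below shControl in its line, the comparisons are of 1 array with 1 array and have no test. The SD of the differences across genes was 0.482 in shGNA12, 0.404 in shGNA13 and 0.402 in shGNAi2. By the probes used, GNA13 at -1.38 lay well beyond it, whereas GNA12 at -0.56 and GNAI2 at -0.39 lay near it. The shGNA12 array had 253 genes at least 1 log2 unit above shControl and 155 below, the shGNA13 array 225 and 55, and the shGNAi2 array 134 and 123. By a rule added after the values were seen, MSRA, a methionine sulfoxide reductase gene, lay 4.78, 4.85 and 4.29 and GDF11 4.43, 3.61 and 4.05 above the shControl array in shGNA12, shGNA13 and shGNAi2, differences that share that 1 array. In shGNA12, MOXD1 lay 5 above shControl. ANKRD1, a YAP-TAZ target gene, stood at -6.40 from shControl, BST2 at -5.80 and CYP51A1 at -3.81. In shGNA13, IGFBP7 lay 4.92 and TNF 4.31 above and TGFBI stood at -2.29, and in shGNAi2 NIBAN1 stood at -5.80. Genes of the unfolded protein and integrated stress response lay above shControl in 22 of 24 cases in shGNA12 (median 0.56), and HIF targets in 20 of 23 (median 0.48), each at percentile 100 among the random lists. These are green signals. On the shGNA12 array the median of red minus green was -0.53 for the stress response and -0.95 for HIF targets. On the shControl array it was -0.02 and -0.55. The lists' differences from shControl in red were not computed, but these values leave less of a rise there than in green. Cholesterol synthesis genes had a median of -0.27 in shGNA12 (percentile 0.06), NF-kB genes 0.42 and interferon response genes 0.43 in shGNA13 (both percentile 100), and SRF-MRTF targets -0.26 in shGNA13 (percentile 0.04). Under the hypoxia label HIF targets in shGNA12 had a median of -0.05 (percentile 28, 9 of 25 above 0), and in shGNA13 the medians were 0.01 for NF-kB genes, 0.08 for interferon response genes and -0.14 for SRF-MRTF targets (percentiles 53.3, 83.43 and 11.62).

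Within the hypoxia label, the 3 differences from shControl share 1 shControl array. The unfolded protein and integrated stress response had a median of 0.82 in shGNA12, 0.39 in shGNA13 and 0.64 in shGNAi2 (each percentile 100). The p53 targets stood at -0.55, -0.36 and -0.27 in the same order (percentiles 0, 0.05 and 3.31). Fibroblast markers stood at -0.63 in shGNA12 and -0.38 in shGNA13 (percentiles 0 and 0.29), and cholesterol synthesis genes at -0.43 in shGNA12 (percentile 0). Under the normoxia label p53 targets and fibroblast markers stood at 0.03 (percentile 69.34) and 0.47 (percentile 98.88) in shGNA12. The fibroblast median rests on 5 members there, against 13 under the hypoxia label. Cell cycle genes had a median of 0.47 in shGNA13 (percentile 100), against 0 under the normoxia label (percentile 92.82), and of 0.28 in shGNAi2 (percentile 99.58). The shGNAi2 array stood apart: 1224 genes lay at least 1 log2 unit above shControl and 1075 below, against 488 and 349 in shGNA12 and 394 and 465 in shGNA13, and its log2 signals correlated with those of the other 3 arrays with r between 0.918 and 0.935, against 0.966 to 0.985 among these. On it SPARCL1 lay 8.34, PDGFA 7.95 (3.42 by a second probe), MGP 7.82 and the matrix protein gene TNC 7.26 above shControl, and DBH, the enzyme that makes noradrenaline, lay -6.52, CHGA -6.08 and the dopamine receptor gene DRD2 -5.84. Fibroblast markers (median 2.04), MAPK output genes (1.83), mesenchymal genes (1.44), interferon response genes (1.21), AP-1 genes (1.15) and cholesterol synthesis genes (1.15) all lay at percentile 100. On the normoxia-labelled shGNAi2 array the medians of these 6 lists were 0.21 (over 5 members), 0.03, 0.12, 0.13, 0.12 and -0.01.

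The 3 knockdown comparisons share the shControl arrays. Across 17051 genes, log2 differences of shGNA12 and shGNA13 correlated with r = 0.676 (covariance 0.167), those of shGNA12 and shGNAi2 with r = 0.5 (0.169), and those of shGNA13 and shGNAi2 with r = 0.473 (0.16). In 100 simulations of unchanged lines with shared controls r was 0.501 and the covariance 0.111, so the covariance exceeded the simulated one by 0.057, 0.058 and 0.049. The 2 control arrays cannot be split, and part of the excess may come from them. In each pair of lines 0 genes were called in both.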

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

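The tests of explanations here were all chosen only after the pattern they bear on was seen, and for the autonomic neuron list alone the test was written before the values of its members were seen.

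The difference between the oxygen labels, 11208 genes, is the first pattern. The dye normalization of the 2-colour extraction protocol was run on the normoxia-labelled arrays alone. Signals from before it gave 11111 genes, which argues against it as the cause. Of the 35 splits of the arrays into 4 and 4, the real one gave 11799 genes without a block and the highest other split 0. The other splits mix the labels, so the label difference enters their error and holds their counts down. The split count therefore restates the separation of the labels and cannot decide on chance. Low oxygen as the whole cause is argued against by HIF target genes, whose highest median among the 4 lines was -0.63, though it stays open as a part. This takes the normoxia label of the green channel as given. On those arrays HIF target genes were brighter in green than in red, and what the red channel held is not stated. RNA of other cells on the hypoxia-labelled arrays is a candidate explanation that these values go with: of 22 autonomic neuron markers, a list chosen once STMN2 and other top genes had been seen, 19 were called higher (median 7.14, or 5.87 with unmeasured members at their bound) and 12 were not well above background on any normoxia-labelled array, with HAND2 at least 379-fold and NEFM at least 263-fold higher and the brightest, TUBB3 and NEFL, at mean levels of 6 and 4.53 (4.31 and -5.06 under the normoxia label), whereas TH, SLC6A2 and INSM1 did not pass (-0.13, or 1.07 by a second TH probe, 0.97 and 1.66). The scan cannot be told apart from the label, and no source names such cells.

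The second pattern is that targeted genes, by the probe used, lay below shControl on the normoxia-labelled arrays and not on the hypoxia-labelled ones. The difference between labels was 0.9 for GNA12, 1.56 for GNA13 and 1.87 for GNAI2, as the sign changed between labels. This difference was not tested. Under the normoxia label the falls of GNA12 (-0.56) and GNAI2 (-0.39) were near the SD of the line differences across genes (0.482 and 0.402). A swap of lines among the hypoxia-labelled arrays is argued against by 2 of the 3 genes, GNA12 and GNA13, for which no array there lay low enough. GNAI2 does not argue against it. Its hypoxia-labelled shControl array lay -0.75 from the mean of the others, beyond the fall of -0.39 on the normoxia-labelled shGNAi2 array. The choice of probe is argued against by the lowest of 5 probes, -0.17 on the log2 scale. RNA of cells without the knockdowns on these arrays stays open. Line differences under one label correlated with those of the same line under the other with r of at most 0.071 across genes. For different lines r was up to 0.1. Such RNA would give this, but so would noise between single arrays or a loss of the knockdown, so the correlations cannot decide. A loss of the knockdown in low oxygen was not tested and stays open.

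The third pattern is a signal in the red channel, which no comparison uses directly. Through dye normalization the green processed signal of the normoxia-labelled arrays depends in part on it. On the normoxia-labelled arrays, HIF target genes were dimmer in red than in green by a median of -0.55 in shControl, -0.95 in shGNA12, -0.42 in shGNA13 and -0.52 in shGNAi2, and they were not alone, as MAPK output genes stood at -0.64, -0.03, -0.81 and -0.62 in the same order. A dye bias that follows signal level is argued against by the random lists matched on mean expression, among which these medians lay at percentile 0 on each array. A fixed dye bias of these genes stays open: the medians ranged over 0.53, above the smallest shift of 0.42, but this rests on the shGNA12 array, without which the range was 0.13. The sources do not state what the red channel held. Across genes, line differences from shControl in red correlated with those in green with r of 0.838, 0.811 and 0.7 in shGNA12, shGNA13 and shGNAi2. Red thus carried much of the same line differences, though the channels share an array. The condition of that RNA is not stated, and no biological explanation was tested.

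Other values stood far from the other 3 arrays of their label. Of 64 sets of 4 arrays, 8 held such a value, of which 7 are given here, where chance marks about 1 in 20. On the normoxia-labelled shControl array 489 spots were left out, against 240 to 280 on the other normoxia-labelled arrays. The mean level of the unfolded protein and integrated stress response genes was 3.119 on the normoxia-labelled shGNA12 array, with the nearest other array at 2.516. Fibroblast markers averaged -3.449 on that array (nearest -4.133). This is a mean over 14 members, of which only 5 were bright enough to enter the single-array medians under that label. On the normoxia-labelled shGNAi2 array, p53 targets averaged -1.141 (nearest -0.876). Ovarian carcinoma markers averaged -1.451 on the normoxia-labelled shGNA13 array (nearest -1.833). On the hypoxia-labelled shGNAi2 array, MAPK output genes averaged 0.896 (nearest -0.543) and mesenchymal genes 1.164 (nearest -0.673).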

How the results depend on the processing

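Fits without both shGNAi2 arrays, on signals before dye normalization and within 1 oxygen label were chosen only after the result was seen, and the other alternatives here were planned.

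The number of genes that differed between oxygen labels stayed within 1.5 times of 11208 under all 15 alternatives run, from 7942 (fold threshold) to 12576 (median centring), and with 1 line left out it was 9044 to 11114. Of the calls, 9076 were shared with median centring, 9095 with quantile normalization, 9858 with normexp and 10934 with signals before dye normalization. Against shControl, the count of 0 genes was 0 in 19 of 20 alternatives for shGNA12, 19 of 20 for shGNA13 and 17 of 19 for shGNAi2, and with single arrays left out it ranged from 0 to 1, 0 to 1 and 0 to 373. The 1 gene was PSMC1 (adjusted p = 0.0441, 0.046 and 0.0434 from limma) without the hypoxia-labelled shControl array, which leaves the normoxia-labelled one as the lone control, where PSMC1 was not well above background. The 373 (228 higher, 145 lower) came without the normoxia-labelled shGNAi2 array, which leaves the hypoxia-labelled one, whose signals stood apart, assumed to vary like the others. Set against the other knockdown lines, shGNA12 gave 0 genes in 19 of 19 alternatives.

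GNA12 passed in 0 of the 19 alternatives that gave a test, and its value of -0.114 was -0.564 on normoxia-labelled arrays alone and 0.336 on hypoxia-labelled arrays alone. With single arrays left out it ranged from -0.586 to 0.358, and it was 0.014 without the normoxia-labelled shControl array and 0.358 without the normoxia-labelled shGNA12 array. GNA13 (-0.597) was -1.378 and 0.184 within the labels and -1.315 to 0.12 with single arrays left out, above 0 without the normoxia-labelled shGNA13 array. GNAI2 (0.541) was -0.393 and 1.475 within the labels and -0.328 to 1.41 with single arrays left out, below 0 without the hypoxia-labelled shGNAi2 array. These changes follow from the opposite signs under the labels, whose cause is weighed among the results for a closer look.

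The number of lists that passed moved more: 0 to 10 for shGNA12 (main 6, within 1.5 times in 16 of 20 alternatives), 0 to 7 for shGNA13 (main 3, 12 of 20), 0 to 15 for shGNAi2 (main 11, 17 of 20), 0 to 12 for shGNA12 against the others (main 4, 15 of 20) and 0 to 14 between oxygen labels (main 9, 12 of 16). It was 0 in each comparison with an estimated correlation; otherwise the cause was not tested. Directions between oxygen labels are relative to a scaling that moved the median of all genes from -0.03 to as low as -0.75. Genes dim on one set of arrays have only bounds there. The oxygen comparison was paired by line, and without that block it gave 11799 genes. By replicate number, no paired analysis was possible because the groups share number 1 alone, and slide or scan as a block was not run, since there was 1 slide and the scan follows the oxygen label.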

Other observations

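All tests and values here were chosen only after the result was seen.

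The red channel of the normoxia-labelled arrays followed the green one closely, with r between 0.994 and 0.995 across spots. Differences of each line from shControl in red correlated with those in green across 13310 genes with r = 0.838 in shGNA12, 0.811 in shGNA13 and 0.7 in shGNAi2, where genes are not independent replicates. The targeted genes stood below shControl in red too, GNA12 at -0.41, GNA13 at -1.14 and GNAI2 at -0.27 (1 array against 1). Between the channels of an array, GNA12, GNA13 and GNAI2 differed by means of 0.01, 0.01 and 0.03. The gene ANKRD37 stood lower in red by a mean of -2.72 ± 0.51 (SD, n = 4 arrays), DDIT4 by -2.38 ± 0.21, PFKFB4 by -2.26 ± 0.52, the glucose transporter gene SLC2A1 by -1.39 ± 0.26, NDRG1 by -1.24 ± 0.34, the adrenomedullin gene ADM by -1.07 ± 0.94 and VEGFA by -0.72 ± 0.24. Each of these was lower on all 4 arrays. Glycolysis genes had medians of -0.11, -0.32, -0.21 and -0.36 on the arrays of shControl, shGNA12, shGNA13 and shGNAi2, at percentiles 1.95, 0, 0 and 0 among random lists, while oxidative phosphorylation genes had medians of 0.02, 0.01, 0.04 and 0.01. Lists other than those of low oxygen also differed between the channels: in the same order of arrays, MAPK output genes had medians of -0.64, -0.03, -0.81 and -0.62 (percentiles 0, 30.62, 0 and 0), AP-1 genes -0.26, -0.09, -0.30 and -0.18, the unfolded protein and integrated stress response -0.02, -0.53, -0.12 and -0.15, and heat shock genes 0.30, 0.06, 0.13 and -0.16. In the other direction GIPR stood higher in red by 1.39 ± 0.28, CYP1B1 by 1.1 ± 0.30 and RASD1 by 1 ± 0.03.

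For the 20 genes per line with the largest green differences on the normoxia-labelled arrays, 20 of 20 had the same sign in red in each line, which shares the array with green, and 14 in shGNA12, 9 in shGNA13 and 12 in shGNAi2 had it under the hypoxia label. These counts cover the largest differences alone and not the gene lists. PSMC1, a proteasome subunit gene, was not well above background on the normoxia-labelled shControl array and stood between 4.28 and 6.41 on the other 7 arrays. UQCRH, a respiratory chain gene, stood at 4.43, 5.82, 1.46 and -3.51 on the normoxia-labelled arrays of shControl, shGNA12, shGNA13 and shGNAi2. On the hypoxia-labelled arrays 20 of the 22 autonomic neuron markers stood lower in shGNAi2 than in the mean of the other 3, such as DDC (-0.03 against 4.23), ISL1 (1.88 against 4.60) and HAND2 (3.44 against 4.02). The other 2, GAP43 (3.49 against 2.96) and SCG2 (0.83 against 0.77), stood higher.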
